A study of Populus tomentosa with 4 samples.

How the data were processed

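Total RNA of shoot tips and surrounding leaves from mature trees grown outdoors was extracted with Trizol and a plant RNA kit and made into Illumina libraries, per the labels' protocols. There were 2 libraries of each tissue. The adapter trimming, aligner, microRNA caller, genome build, counting, scaling, target predictor and test are not given in the sources used here.

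The values used came from 1 table of the authors' comparison. Each tissue has 1 signal per microRNA name, a normalized read abundance that the authors formed from both libraries; its scale is not stated. The authors also gave a log2 fold change of shoot tips over leaves and an FDR, an adjusted p-value, in the deposited table. The table had 27252 lines, 1 for each microRNA and predicted target, and 1215 of them repeated another line. Each microRNA was read once. For 111 of the 132 names above 0 in both tissues, the log2 fold change lay within 0.1 of the log2 ratio of both signals, and the largest gap was 0.90. Of 107 sequences, 37 had several names, and for 22 of these the names had different values. The rule by which reads were assigned to names is not stated, so values of names with 1 sequence are uncertain. There were 42 names listed at 0 in shoot tips and 19 in leaves. Target loci carry P. trichocarpa-style identifiers and a Swiss-Prot description for all but 2140 of 10305; 0 of them matched the reference gene table, so the table's own descriptions were used.

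The planned tests needed a value per library and could not be run on 1 pooled signal per tissue. The branch fixed before the data were examined for such a table was followed instead: no test of the tissue difference of single microRNAs was added, and the authors' FDR below 0.05 was the threshold. Fisher's exact tests of length, first base and target classes and a permutation over families were added after the values were seen. Each list of at least 5 members was placed by its median log2 fold change as a percentile among 10000 random lists of the same size, drawn within 4 quartiles of level, as a description with no p-value. There were 13 microRNA lists, defined by family number, and 21 lists of genes, defined by description; both were fixed before the data were examined. Gene lists, markers of other cell types included, could be applied to predicted target loci alone, since no messenger RNA was measured. Their balance between both directions was compared with 100000 permutations of direction over 87 units of sequences, for lists with at least 5 loci.

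Named microRNAs were chosen by a rule fixed before the data were examined. It took per direction the 8 largest absolute log2 fold changes with a signal of at least 5 in the higher tissue, 1 per family, the 2 members of each list with the smallest FDR, and the 3 highest levels; 36 names were taken. Numbered microRNAs carry no family name or description and were left out of the first part. Other microRNAs given with values, such as further names of 1 sequence and those of the closing section, were chosen after their values were seen.

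The reads of the 2 unlabelled libraries behind each signal up to 5000 were sought, mainly for the closing section. They were recovered for 178 names in shoot tips and 177 in leaves, those listed at 0 included, and not for every signal up to 5000. A signal was taken as a sum of whole multiples of 2 steps, searched between 0.15 and 1.5, and a solution was kept when it lay within 1.2 times the rounding error of the last printed digit and the next best lay at least 10 times farther off. Several pairs of steps fitted, 6 for shoot tips and 2 for leaves, and the coarsest was used. On simulated data with known reads, 81 of 81 kept shoot tip solutions and 79 of 79 kept leaf solutions were right. Which replicate each library is remains unknown. No test of tissues was run on these reads, since every listed microRNA had already been selected by the authors' FDR. Their intervals cover counting error only. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.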

Results

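Small RNA was sequenced from shoot tips, which the labels also call SAM, and from surrounding leaves of Chinese white poplar (Populus tomentosa), with 2 libraries per tissue and 4 in all. The series asks which microRNAs are present in the 2 tissues and differ between them. MicroRNAs are short RNAs that guide the cleavage or silencing of matching transcripts. The table used here held 1 value per tissue, a log2 fold change of shoot tips over leaves and an adjusted p (FDR) for each microRNA, together with its predicted target loci. No value per library was given, so no SD over replicates accompanies the values, and each difference rests on the authors' FDR. Nothing in the labels says whether the 2 libraries of a tissue came from separate trees, so those FDR values may measure technical spread alone.

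The authors' deposited table listed 193 microRNA names, all with an FDR below 0.05, the largest being 0.0493. It held 105 names of 30 known families and 88 names that carry only a running number, called numbered microRNAs here. Many names share 1 mature sequence and then repeat its reads, so the 193 names stood for 107 distinct sequences, 52 known and 55 numbered. The depth of each library is not stated in the table. Summed over distinct sequences, the listed values came to 507339 in shoot tips and 393681 in leaves, which is not the depth, since only microRNAs called different were listed.

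Shoot tips were marked by the miR159 and miR319 families, miR171, miR1446, miR390 and miR394, of which only the 3' arm was listed. Leaves were marked by miR396, miR172, miR393, miR164 and a set of strongly leaf-biased families, miR397, miR398, miR408 and miR1444. Of the 193 names in the authors' deposited table, 73 were higher and 120 lower in shoot tips. Counting each mature sequence once gave 45 higher and 62 lower, and the 105 known names divided into 47 higher and 58 lower. All listed names of 9 families were higher in shoot tips, all those of 19 families were lower, and 2 families, miR171 and miR3627, had names in both directions. Leaving miR159 and miR319 out of the total was a check chosen after the values were seen, with the values taken as RPM. It would raise every other log2 fold change by 0.70. Such a shift could reverse no listed name, since the smallest absolute log2 fold change was 1.10.

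**Figure D1:**
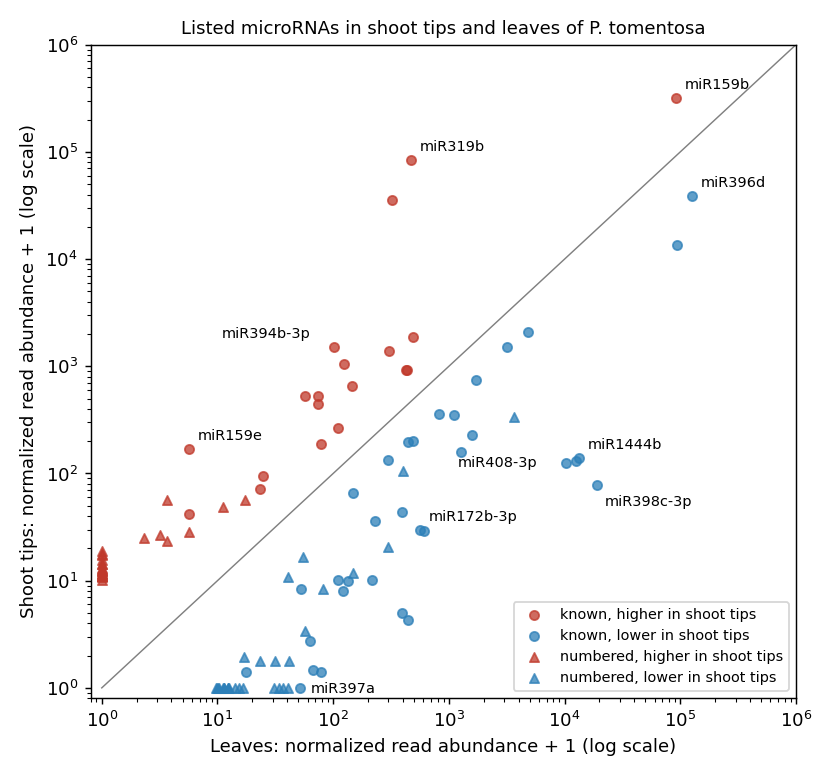
Normalized read abundance plus 1 in leaves (horizontal, log scale) and shoot tips (vertical, log scale) of the 107 distinct mature sequences in the authors' deposited table, 1 point each, circles for known and triangles for numbered microRNAs, red for higher and blue for lower in shoot tips. Points above the grey line of equal values are higher in shoot tips; miR159b reached 317060 in shoot tips and 90918 in leaves, and points on an axis edge are listed at 0 in that tissue.

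The miR159 and miR319 families, related microRNAs known to target GAMYB-type MYB factors and TCP factors of leaf growth, were higher in shoot tips in all 14 listed names. In the authors' deposited table miR319b stood at 84092 in shoot tips and 468 in leaves, a log2 fold change of 7.46 (FDR 8.99e-116). MiR319e and miR319h had 35824 and 323 (log2 fold change 6.77, FDR 4.66e-118) in the authors' deposited table, while miR319f and miR319g, with the same sequence, had 41380 and 921 (log2 fold change 5.47). The most abundant microRNA by its mean over both tissues, miR159b, had a smaller difference, with 317060 in shoot tips and 90918 in leaves and a log2 fold change of 1.80 (FDR 8.26e-08) in the authors' deposited table; miR159a was almost equal to it at 317047 and 90908. MiR159e was far less abundant, at 167.3 against 4.64, with a log2 fold change of 5.06 (FDR 2.47e-13) in the authors' deposited table. The median log2 fold change of the 14 names was 5.47, above all 10000 random lists of the same size matched on level, and the 7 distinct sequences had a median of 3.07, at percentile 99.8. Members of these families differ at few bases (miR159e at 3 positions and miR159d at 2 from the nearest miR319 sequence), and the table does not say how reads matching several were assigned.

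The miR171 family, which targets scarecrow-like GRAS factors of the shoot meristem, had 7 listed names higher and 1 lower in shoot tips. The lower name, miR171l-5p, is by its name a 5' arm with a sequence of its own (log2 fold change -1.17 in the authors' deposited table). MiR171i had 532 in shoot tips and 55.7 in leaves (log2 fold change 3.24, FDR 1.30e-13), and miR171e had 543 and 59.9 (log2 fold change 3.17, FDR 2.91e-13) in the authors' deposited table. The median of the 8 names was 3.04, at percentile 99.985 of matched random lists. These names stand for 3 sequences, too few to be compared by sequence, so this placement rests on names that repeat reads.

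The listed microRNAs of the meristem and polarity list and of the auxin list did not move as groups. No name of miR165 or miR166 was listed, so the meristem and polarity list rests on miR164 and miR394 alone. The 3' arm of miR394 was higher in shoot tips, with miR394b-3p at 1499 against 100.3 (log2 fold change 3.87, FDR 1.18e-23) and miR394a-3p at 1520 against 116 (log2 fold change 3.68, FDR 4.61e-22) in the authors' deposited table, while all 5 miR164 names, known to target NAC factors of organ boundaries, were lower. The median of these 7 names was -2.96 (percentile 3.93), but over the 2 sequences it was 0.44, so its sign depends on the unit. In the auxin list, 8 names of miR160 and miR390 were higher and 3 names of the miR167 3' arm were lower (median 1.26, percentile 88.9). These 11 names stand for 3 sequences, too few to be placed by sequence, so the percentile rests on names that repeat reads. MiR390a, which starts the production of small RNAs against auxin response factors, had 650 in shoot tips and 144 in leaves (log2 fold change 2.16, FDR 2.39e-07), and miR167h-3p had 8.86 and 134 (log2 fold change -3.88, FDR 1.69e-09) in the authors' deposited table; names with the same sequence as the latter reached -3.11. All 3 miR393 names, which target the TIR1/AFB auxin receptors, were lower, with miR393c at 9.25 against 214 (log2 fold change -4.49, FDR 1.78e-15) and miR393a-5p at 5.94 against 84.7 (log2 fold change -3.78, FDR 2.22e-06) in the authors' deposited table; they share 1 sequence, and their values differ although the sequence is the same. The recovered shoot tip libraries of miR393a-5p were at 2.36 and 9.52, from 3 and 10 reads.

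MiR396 and miR172, which act in leaf growth and the timing of development, were lower in shoot tips. The 7 miR396 names, which target growth-regulating factors of cell proliferation, had a median log2 fold change of -1.70 (percentile 20.5). They stand for 4 sequences, too few to be placed by sequence. In the authors' deposited table miR396a and miR396b had 13389 in shoot tips and 93155 in leaves (log2 fold change -2.79, FDR 1.20e-17), and miR396d, the most abundant leaf microRNA listed, had 38747 and 126570 (log2 fold change -1.70, FDR 3.79e-08). The 4 miR172 names, which target APETALA2-type factors, share 1 sequence, and miR172b-3p and miR172f had 28.5 in shoot tips and 560 in leaves (log2 fold change -4.27, FDR 1.70e-17) in the authors' deposited table; their recovered shoot tip libraries were at 14.2 and 42.8. The list of miR156 and its relatives, which precede miR172 in phase change, had 0 members in the table and was not analysed here.

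MicroRNAs tied to copper and phosphate supply were the most leaf-biased list, with 9 of 9 names lower in shoot tips. Their median log2 fold change was -6.65, below all 10000 matched random lists, and at percentile 0.04 over 7 distinct sequences. In the authors' deposited table miR398c-3p, which targets copper/zinc superoxide dismutases, had 77.4 in shoot tips and 19229 in leaves (log2 fold change -7.93, FDR 1.05e-115), and miR398b was nearly equal to it at 77.4 and 19224. MiR408-5p, the arm opposite to the one that targets laccases and blue copper proteins, had 0.394 and 76.9 (log2 fold change -6.90, FDR 5.88e-07) in the authors' deposited table; its shoot tip value corresponds to 1 recovered read, so the ratio of 195 has an exact 95% counting interval of 34.5 to 7771, and with a pseudocount of 1 its log2 ratio was -5.80. MiR397a, which targets laccases, was listed at 0 in shoot tips and 51.1 in leaves (FDR 3.34e-06) in the authors' deposited table, and its fitted fold sets no bound. With miR397a placed at the value of 3 reads, the list's median was -6.34. MiR1444 of poplars, which targets polyphenol oxidases, was on another list, where miR1444d and miR1444e had 131 and 12557 (log2 fold change -6.55, FDR 2.80e-66) in the authors' deposited table. Their sequence is complementary to that of miR1444b over 20 nt, and whether reads were counted by strand is not stated, so their values are uncertain; their recovered shoot tip libraries were at 81.9 and 179.9. That list of Populus microRNAs had 5 names higher, all miR1446, and 9 lower, with a median of -1.94 (percentile 16.1). Counted by sequence it had 1 higher and 6 lower, with a median of -3.51 (percentile 6.49). MiR1446b had 1383 in shoot tips and 305 in leaves (log2 fold change 2.17, FDR 7.38e-08) in the authors' deposited table, while miR1446d, with the same sequence, had 699 and 221 (log2 fold change 1.65).

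**Figure D2:**
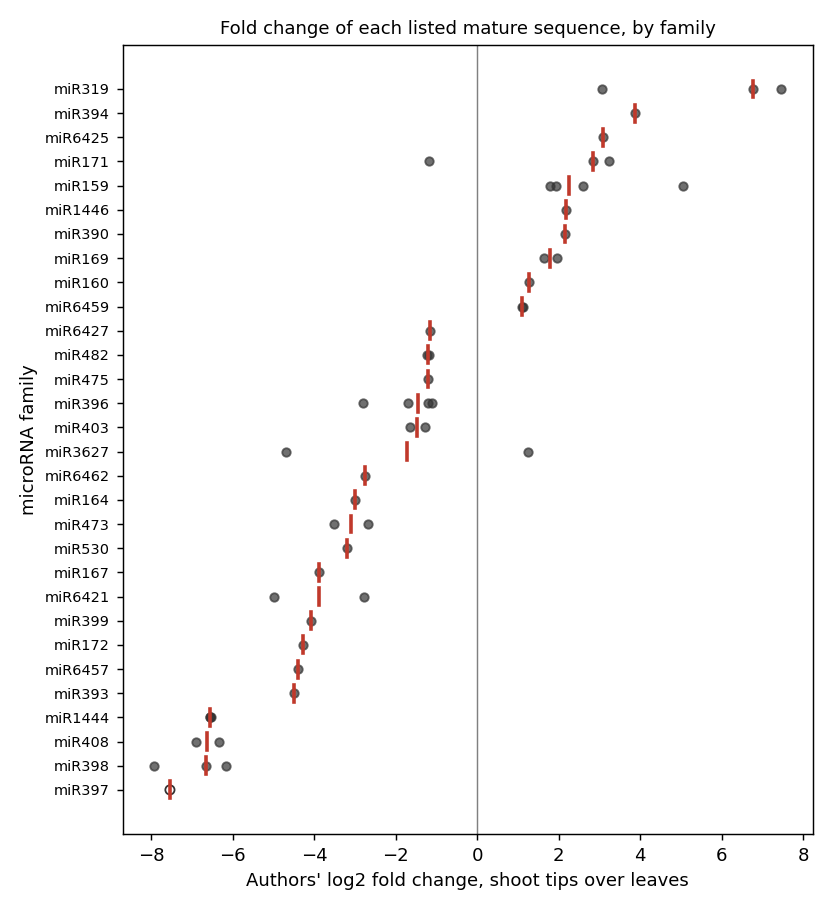
The authors' log2 fold change of shoot tips over leaves (horizontal) for each distinct mature sequence of the 30 known families (rows), with a red bar at the family median; the open circle is miR397a, listed at 0 in shoot tips. MiR319 lies at the top with a median of 6.77, and miR1444, miR408, miR398 and miR397 lie at the bottom, where the 11 names above 0 in shoot tips lie between -6.15 and -7.93 and miR397a would lie at -5.16 with 3 reads.

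The listed families of the small RNA machinery and disease resistance lists, miR403 and miR482, had smaller differences. No other family of either list, such as miR162 or miR168, was listed, so their values are not known. The 5 miR403 names, whose family is known to target an Argonaute gene, were lower in shoot tips (median -1.28, percentile 44.5). They stand for 2 sequences, too few to be placed by sequence. In the authors' deposited table miR403c-5p, the arm opposite to miR403c-3p, had 350 against 1104 (log2 fold change -1.65, FDR 1.14e-06). MiR403a, with the sequence of miR403c-3p, had 201 against 490.3 (log2 fold change -1.28, FDR 0.0199) in the authors' deposited table. The recovered shoot tip libraries of miR403a were at 117 and 286, and against the higher one alone leaves were 1.72-fold higher; 4 of the 6 lower names that fell under 2-fold without the other library were miR403. MiR482c-3p, of a family that targets disease resistance genes, had 2071 and 4840 (log2 fold change -1.22, FDR 0.000551), and miR482d-3p had 195 and 446 (log2 fold change -1.18, FDR 0.00399) in the authors' deposited table. With miR159 and miR319 left out of the total, miR482c-3p and miR482d-3p had log2 fold changes of -0.52 and -0.49. MiR403a and miR403c-5p then had -0.58 and -0.95, so much of these small falls depends on the total used. The 3 miR169 names, of a family that targets nuclear factor Y subunit A, were higher, with miR169ae and miR169af at 94.4 against 23.9 (log2 fold change 1.95, FDR 0.00533) in the authors' deposited table. Among families without a fixed list, miR6425e was higher in shoot tips at 40.8 against 4.64 (log2 fold change 3.08, FDR 0.00477), and miR6421-5p, miR3627b and miR6457b were lower, at 1.74 against 62.3, 0.394 against 16.6 and 28.2 against 608, in the authors' deposited table; the shoot tip value of miR3627b corresponds to 1 recovered read, and the leaf value of miR6425e to 3 and 5 reads in the 2 libraries, or 2.65 and 6.64. Of the 8 lists large enough to be placed by names, 3 lay outside the central 95% of random lists; by sequence 3 lists could be placed and 2 lay outside it.

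The predicted targets in the table held the textbook classes for most families. Among 10305 distinct predicted loci, disease resistance proteins made up 155 of the 308 loci of miR482, or 50.3%, against 1.86% of the other loci, and pentatricopeptide repeat proteins made up 63.7% of the loci of miR475. Laccases were 33 of 179 loci of miR397, growth-regulating factors 18 of 305 of miR396 and polyphenol oxidases 12 of 326 of miR1444. TCP factors were 7 of 293 loci of miR319, GAMYB-type factors 7 of 506 of miR159, TIR1/AFB receptors 7 of 142 of miR393 and APETALA2-type factors 6 of 154 of miR172. For 16 of 18 such classes the share exceeded that among other loci (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p below 0.05 over the 18); the classes were chosen after the annotations were seen. No auxin response factor was predicted for the listed miR167, which is its 3' arm (0 of 134), and no Argonaute gene for miR403 (0 of 295). Loci predicted for related sequences overlap and are not independent, and a predicted locus is not a measured transcript.

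No gene list was tied to 1 direction after correction. Predicted loci numbered 4544 for microRNAs higher in shoot tips and 6900 for those lower, with 1139 in both sets. Directions were permuted over 87 units, each 1 numbered sequence or the names of 1 known family in 1 direction. Related sequences, such as those of miR159 and miR319, stayed in separate units and can share loci, so the units are not independent. Of 19 gene lists compared, 0 had an adjusted p below 0.05 and 1 had an unadjusted p below 0.05. That list, heat shock proteins, had 2 loci predicted for higher and 20 for lower microRNAs (two-sided permutation p 0.00944, Benjamini-Hochberg adjusted p 0.179). Growth-regulating factors had 3 and 19 (p 0.691), TCP factors 7 and 7 (p 0.703), and xylem and secondary wall genes 25 and 56 (p 0.589).

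Numbered microRNAs differed in length by direction, while known ones did not reach 24 nt in either. Of 26 numbered sequences higher in shoot tips, 23 were 24 nt long (88.5%), against 5 of 29 lower ones (17.2%; Fisher's exact test, two-sided, p 9.92e-08), a test chosen after the values were seen. In the authors' deposited table the 23 had low values, from 9.09 to 55.3 in shoot tips, and 18 were listed at 0 in leaves. Reads recovered per library from the pooled values, with the coarsest steps that fitted, put 24-nt sequences lower in 1 shoot tip library than in the other (median log2 ratio -0.87, 3 of 24 higher) and known sequences higher in it (median 0.69, 40 of 42 higher); under 2 of the 6 pairs of steps that fitted, both classes had medians of the same sign. Known sequences were 20 to 22 nt long in both directions.

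**Figure D3:**
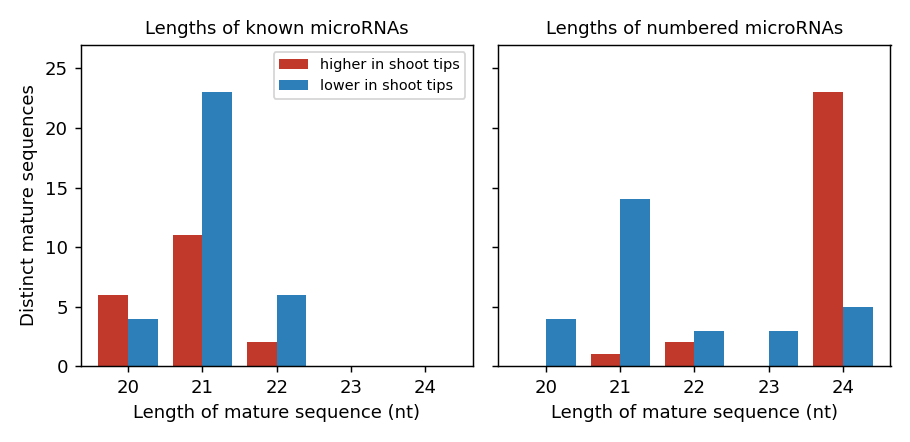
Number of distinct mature sequences (vertical) by length in nt (horizontal) for known microRNAs (left) and numbered microRNAs (right), red for higher and blue for lower in shoot tips. Of the numbered sequences, 23 higher and 5 lower ones were 24 nt long, and no known sequence was.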

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

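The alternatives that count each sequence once, take known names alone, leave out miR159 and miR319, use recovered libraries, leave 1 of these out or use a pseudocount were chosen after the data were seen. Against 73 names higher and 120 lower, the microRNAs above the median level gave 42 and 54, each sequence once gave 45 and 62, and known names alone gave 47 and 58; each of these counts fewer microRNAs by construction. An FDR below 0.01 gave 50 and 88. Leaving miR159 and miR319 out of the scaled total gave 73 and 107 with at least a 2-fold change. Of 3 lists outside the central range by names, 2 were outside by sequence, and the miR171 list had too few sequences to be placed. With a pseudocount of 1, 3 lists were outside. None of the 36 named microRNAs reversed with that pseudocount or without miR159 and miR319, but neither check could reverse a name. A pseudocount keeps the order of the 2 values, and the shift of 0.70 is below the smallest absolute log2 fold change, 1.10. Leaving out miR159 and miR319 moved 29 of the 36 names beyond their counting interval. The shift was the same for every name, so this count reflects how many reads a name had. Names of the families left out, such as miR159a and miR319b, were among the 29. No paired analysis was possible because the 2 tissue columns carry no replicate numbers. Leaving out 1 library in turn was run on reads recovered with the coarsest steps, as the number of names at least 2-fold apart in the listed direction; it gave 61 to 63 higher and 100 to 106 lower, among 63 and 106 recovered. The planned normalizations, count and limma-type models and low-value filters per library were not run, since the table gives no value per library and recovered reads cover only microRNAs already selected by FDR. Many numbered microRNAs rest on few reads in 1 tissue and on 0 in the other, with 41 names listed at 0 in shoot tips and 19 in leaves. Whether depth explains these zeros was not tested.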

Other observations

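All tests in this part were chosen after the results they measure were seen. Families linked to copper supply had the most negative folds among known names. MiR397, miR398 and miR408 lower the amounts of copper proteins such as laccases and superoxide dismutases when copper is short, and miR1444 does so for polyphenol oxidases. Of their 12 names (9 sequences), the 11 above 0 in shoot tips had log2 fold changes from -6.15 to -7.93 in the authors' deposited table, and miR397a, listed at 0, would have -5.16 with 3 reads. The most negative of any other known name was -4.99 in the authors' deposited table, so the gap is small for miR397a. With a pseudocount of 1 the 12 names ranged from -5.50 to -7.94, and the most negative other known name was at -4.53. Another 11 numbered names, all listed at 0 in shoot tips, had fitted folds in the same range in the authors' deposited table. MiR399f, of a family that answers phosphate shortage, had a log2 fold change of -4.07 in the authors' deposited table.

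A dilution of other microRNAs by miR159 and miR319, which made up 44.0% of the total in shoot tips if values are taken as RPM and 9.24% in leaves, would shift them by 0.698 on the log2 scale, far less than the falls. One outlying library stays open as an explanation of the pattern as a whole, since 5 of the 9 sequences could not be compared by library. Selection by the authors' FDR fixed that both leaf libraries lay above both shoot tip libraries, and these families were picked for their large folds. Only the size of the gap can therefore be described. For 3 sequences of miR398 and miR408 with recovered reads above 0, the lower leaf library was at least 57.5 times the higher shoot tip library. Under every pair of steps that fitted, it was at least 23.1 times as high. The smallest ratio, of miR398c-5p, rests on 1 shoot tip read, with a lower counting limit of 7.91 under the coarsest steps. MiR397a had 0 reads in both shoot tip libraries and 54 and 41 in the leaf libraries. The falls of these sequences thus did not rest on 1 library alone. For the other 5 of 9 sequences, all 3 of miR1444 among them, no leaf reads were recovered, so the libraries could not be compared. A lower copper supply of leaves may lie behind the pattern, but copper was not measured. The mean of the 4 family medians was -6.84 (-6.25 with miR397a at 3 reads), against -2.90 for the other leaf-higher families, and a permutation p of 0.000258 is the smallest possible one and was fixed by picking the lowest families, so it decides nothing.

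The length pattern of the numbered microRNAs had a candidate explanation in 24-nt siRNA-type RNAs, which usually start with A. Of 28 numbered sequences of 24 nt, 19 started with A (67.9%), against 3 of 27 others (11.1%; Fisher's exact test, two-sided, p 2.22e-05). Low read numbers were tested first by the share of 24-nt sequences among leaf-higher ones with values under 20, which was 21.4% (3 of 14, exact 95% interval 4.66 to 50.8) and left this open, since the interval reached past the bound of 50% used; a second comparison, with 18 of 19 shoot-tip-higher ones at the same level, gave p 1.97e-05 (Fisher's exact test, two-sided), but it was added after the first had left the question open. A single shoot tip library stays open: 100% of the 23 sequences had both shoot tip libraries above both leaf libraries, but selection by the authors' FDR fixed this, and the 24-nt sequences were lower in 1 shoot tip library than in the other under the coarsest steps. The design has no mutant or Argonaute sample that would test the biological reading.

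The tissue values behaved as sums of whole multiples of 2 steps. This fits means of 2 libraries scaled to a common total, as steps chosen on every other value up to 60 made 100% of the values left out (26 in shoot tips, 21 in leaves) whole within 1e-06. A chance coincidence is argued against, since 0% of 40 sets of decoy values, each with its own search, had a pair of steps that made all values whole. If the values are mean RPM, the totals behind the libraries were 1270332 and 1050682 for shoot tips and 1133180 and 752959 for leaves; finer steps also fitted, and a sum in place of a mean would double the totals.

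The 2 shoot tip libraries, called first and second by their step size alone, had different ratios by class of RNA. The median log2 ratio of the second to the first was 0.69 for 42 known sequences, 40 of them higher in the second, and -0.87 for 24 numbered sequences of 24 nt, 3 of them higher in the second. These ratios hold for the coarsest steps. Over the 6 pairs of steps that fitted, the medians of both classes differed by 0.94 to 1.56, while under 2 of the pairs both medians had the same sign, at 2.48 (known) and 1.54 (24 nt) under 1 and at -0.82 and -1.94 under the other, so the opposite directions depend on the steps. A permutation over sequences under the coarsest steps gave p 1e-05, the smallest it can give, but sequences are not replicates of a library, so it decides nothing about the libraries. In leaves the medians were 0.12 and 0.0048 with the coarsest steps and 2.24 and 2.31 with the other pair.

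With the coarsest steps, some values lay mostly in 1 library. The numbered sequence m0531-5p had 66 reads in 1 leaf library and 2 in the other, and m2623-3p had scaled values of 1869 and 5401 in the leaf libraries. Of the 24-nt sequences higher in shoot tips, m2175-5p had 28 and 2 reads in the shoot tip libraries and m1702-3p had 22 and 3. Others were more even, such as m0713-3p with 19 and 15. MiR398a had 0 and 7 reads in the shoot tip libraries and scaled values of 423 and 459.5 in the leaf libraries, with an FDR of 0.00156 in the authors' deposited table. MiR399f had 2 and 13 reads in shoot tips.

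Pairs of known mature sequences that are complementary over at least 16 nt had nearly equal values. There were 2 such pairs. Whether reads were counted by strand is not stated, so the values of either member are uncertain, miR1444d among them. MiR1444d and miR1444b, complementary over 20 nt, had 131 and 140 in shoot tips and 12557 and 13289 in leaves in the authors' deposited table. MiR6459a-3p and miR6459b, complementary over 18 nt, had 930.3 and 930.3 in shoot tips and 429 and 429 in leaves in the authors' deposited table. Names with 1 mature sequence did not always have 1 value, as miR319e and miR319f differed 2.85-fold in leaves.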
